A study of Capra hircus with 2 samples.

How the data were processed

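Small RNA was profiled by sequencing in natural killer (NK) cells of female goats. One library came from NK cells separated from the uterus (uNK) and one from NK cells separated from peripheral blood (pNK). RNA was extracted with Trizol per the labels' protocols. The library kit, read length, aligner, counting tool, genome build and miRNA annotation are not given in the sources used here, and neither is the number of animals behind a library or any marker used for the separation. Groups were taken from the source names of the 2 samples. With 1 library per group there is no spread between replicates, so no p-value was computed between the groups.

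The analysis started from 1 table of the authors' comparison, which is named for the DEGseq method and for a filter on differential expression. It holds 590 mature miRNAs, of which 314 carry goat miRNA names and 276 are numbered predicted miRNAs. Per the file headers, 2 columns hold read counts, which are whole numbers. Another 2 columns are headed as expression and behave as RPM values (reads per 1000000 reads of the library) in the deposited table. Count divided by value was the same, up to the rounding of the values, for every miRNA with at least 5000 reads in a library. A count of 0 is written as 0.001. The remaining columns hold the authors' log2 ratio of uNK over pNK, a direction, a p-value and a q-value, per the file headers. In the deposited table no absolute log2 ratio is under 1.01 and no q-value is above 0.000815, so a miRNA missing from it was either not called or not detected, and nothing is said here of such miRNAs. The authors' deposited log2 ratio equals the log2 ratio of the counts, with 0.5 in place of a count of 0, plus a constant of 0.27. That scaling lies 0.35 log2 above the scaling of the RPM columns. It is close to the ratio of the 2 libraries' totals over the listed miRNAs.

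Library totals implied by the RPM columns were 30063448 reads for pNK and 31780927 for uNK. The listed miRNAs took 14291082 reads of pNK and 11884560 reads of uNK. Folds were computed as ratios of RPM values, with exact Clopper-Pearson 95% intervals on the 2 counts. Where 1 library had a count of 0, a floor of 3 counts in that library (0.0998 RPM in pNK and 0.0944 RPM in uNK) gave a lower bound of the fold. No molecular identifiers are mentioned, so intervals and floors cover counting error only, not the differences between animals, preparations or libraries, which cannot be measured here. For list medians and for ranking, log2 values were computed after adding 1 RPM to both libraries, which understates the change of low miRNAs. Whether a miRNA counts as higher or lower follows the direction in the authors' deposited table.

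The design, the 15 lists of miRNAs by cell type, cluster or family, and the rule for the miRNAs named were fixed before the data were examined. The lists cover muscle, smooth muscle and stroma, epithelium, ciliated epithelium, endothelium, erythroid cells, myeloid cells and platelets, lymphocytes, the miR-17-92 clusters, let-7, inflammation and activation, the X-linked miR-424 cluster, the DLK1-DIO3 imprinted cluster, the Hox clusters, and liver as a control. A list took every listed arm of its miRNAs. Named were miR-1, which is in the study's title; the 8 annotated miRNAs with the largest positive and the 8 with the largest negative log2 value among those with at least 100 counts in the higher library; the 5 most abundant annotated miRNAs of each library; and the 3 most abundant members of each list. Each list's median was placed among the medians of 10000 random lists of the same size. These were drawn from the table and matched on abundance in 5 bins. The percentile describes these 2 libraries and is not a test across animals. Random lists drew miRNAs singly, whereas arms and neighbouring genes on a list can move together, so a percentile can look more extreme than it is. The background also held the predicted miRNAs, which were mostly lower in uNK. On simulated counts for 590 miRNAs, 100% of 100 lists of 8 members shifted by 2 log2 units lay above the 97.5th percentile. Of 100 unshifted lists, 4% lay outside the central 95%. The simulated miRNAs varied independently and passed no filter, unlike the listed ones, so these rates need not hold for the lists used here. For precursors with both arms listed and at least 10 reads per arm over both libraries, the log2 ratio of the 5p over the 3p count was compared between libraries after adding 0.5 counts.

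Alternatives were a stricter threshold (2 log2), filters at 10 and 100 counts, scaling to the listed totals, to the median ratio or by TMM in edgeR 4.0.16 (R 4.3.3), pseudocounts of 0.5 and 5 RPM, annotated miRNAs only, arms and loci summed, and unmatched random lists. The other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots matplotlib 3.10.9. A gene table of the goat assembly ARS1.2 served only to find which miRNA genes are neighbours; no coordinates are given because the build behind the deposited table is not named. Messenger RNA targets were not analysed here.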

Results

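MicroRNA profiles were compared between NK cells of the goat uterus and NK cells of goat blood. The study's title names miR-1 and its target TWEAK, a cytokine of the tumour necrosis factor family. There was 1 library per group. The pNK library held 30063448 reads and the uNK library 31780927, as implied by the deposited values. The listed miRNAs took 47.5% of the pNK reads and 37.4% of the uNK reads. Each comparison is therefore one between 2 libraries, without a replicate check, and the intervals given are 95% Clopper-Pearson intervals for counting error.

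miR-1, a miRNA best known from muscle, was 12.0-fold higher in the uNK library (interval 11.5 to 12.5), at 916 reads per 1000000 reads of the library (RPM, 29105 reads) against 76.4 RPM (2297 reads). Its fold was close to those of the other muscle-enriched miRNAs. This was not particular to muscle: miR-200c of the epithelial list was 12.6-fold higher and miR-424-5p of the X-linked list 13.7-fold higher. miR-133a-3p was 13.6-fold higher (12.6 to 14.7) and miR-133b 13.0-fold higher (11.0 to 15.5). All 4 listed members of the muscle list, including miR-206, were higher in uNK, and their median log2 value of 3.51 lay at the 97.7th percentile of matched random lists. The log2 value of miR-1 was 3.57 on the RPM scale and 3.93 in the authors' deposited table. Other scalings placed it between 2.90 and 4.31. These were computed only on miRNAs called different, so they do not rest on unchanged miRNAs. The pNK count of miR-1 was 7.89% of its uNK count, and the median share over the 4 muscle-enriched miRNAs was 7.16%.

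Among the listed miRNAs, the 2 libraries were led by different ones. Only miRNAs called different are listed, which favours such a contrast, and abundant miRNAs that were not called could not be ranked. miR-143-3p, which is abundant in smooth muscle and stromal cells, took 45.2% of the listed uNK reads (45.18 to 45.24%) and 2.42% of the listed pNK reads. It was 14.7-fold higher in uNK (14.6 to 14.7), at 169065 against 11522 RPM. miR-21-5p, a miRNA induced by inflammation, took 33.9% of the listed pNK reads (33.87 to 33.92%) and 6.56% of the listed uNK reads, and was 6.57-fold lower in uNK (6.56 to 6.59). After miR-21-5p, the most abundant listed miRNAs of pNK were miR-27a-3p, miR-191-5p, miR-223-3p and miR-16a-5p. They were 4.89-fold, 25.8-fold, 1508-fold and 19.2-fold lower in uNK. After miR-143-3p, the most abundant listed miRNAs of uNK were let-7b-5p, miR-21-5p, miR-27b-3p and miR-126-3p. Of these, let-7b-5p was 4.46-fold higher in uNK (4.43 to 4.48), miR-27b-3p 5.24-fold (5.21 to 5.28) and miR-126-3p, an endothelial miRNA, 5.99-fold (5.93 to 6.05). The 10 most abundant listed miRNAs took 76.9% of the listed reads in pNK and 79.0% in uNK.

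In the authors' deposited table, 224 miRNAs were higher and 366 lower in uNK. Annotated and predicted miRNAs divided differently. Of the 314 annotated miRNAs, 170 were higher and 144 lower. Of the 276 predicted miRNAs, 54 were higher and 222 lower, and 175 of those lower had no read in uNK. Predicted miRNAs took 3.99% of the listed reads in pNK and 0.511% in uNK. On the RPM scale no direction changed, and 11 of the miRNAs called higher lay under a log2 difference of 1.

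**Figure D1:**
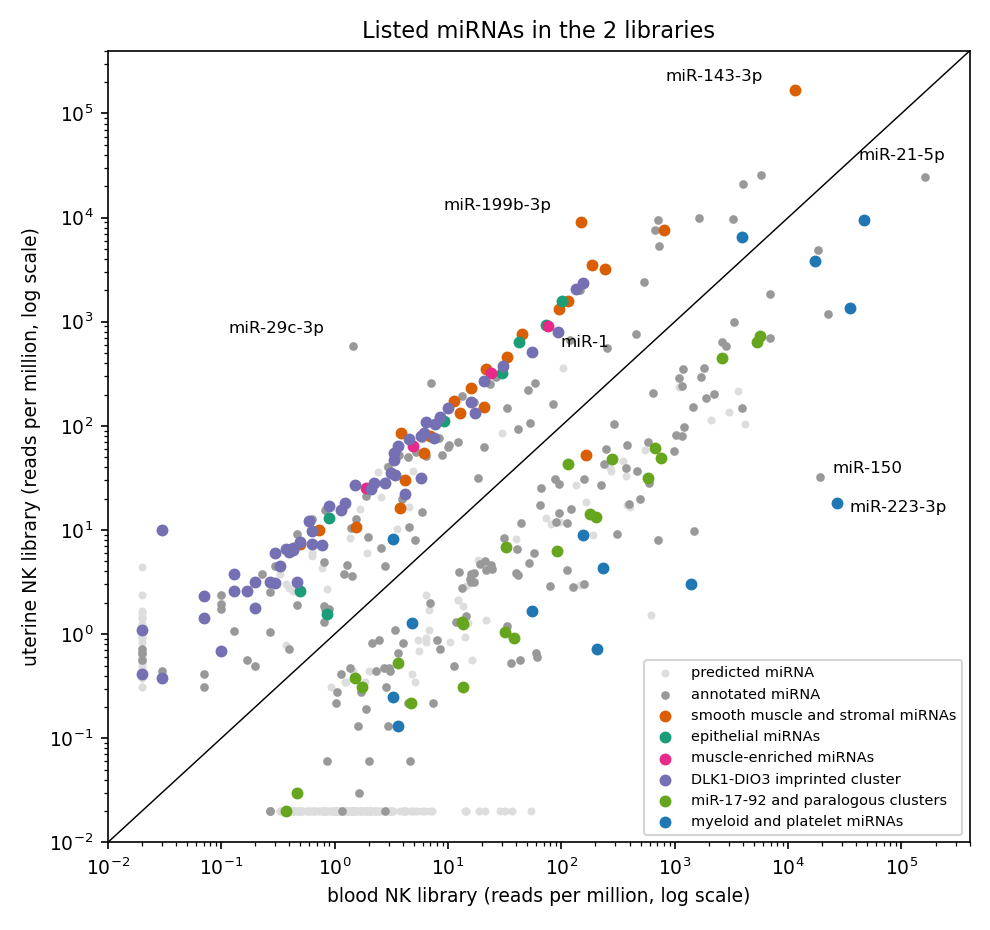
Each point is a listed miRNA, with its level in the blood NK library on the horizontal axis and in the uterine NK library on the vertical axis, both in RPM on log scales, with counts of 0 drawn near the lower edge and the line marking equal levels. The members of the stromal, epithelial, muscle and DLK1-DIO3 lists lie above the line, except miR-10a-5p of the stromal list at 165 RPM in blood NK and 52.3 in uterine NK; miR-29c-3p and miR-199b-3p have the largest uterine levels for their blood levels among the labelled points.

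Stromal and epithelial miRNAs were higher in the uNK library. Of the 23 listed members of the smooth muscle and stromal list, 22 were higher and 1 lower, with a median log2 value of 3.70 at the 100th percentile of matched random lists. Beside miR-143-3p its most abundant members were miR-199b-3p, 60.7-fold higher (58.9 to 62.5), and miR-99a-5p, 9.48-fold higher (9.35 to 9.61). The exception was miR-10a-5p, which lies in a Hox gene cluster and was 3.15-fold lower (2.98 to 3.34). All 8 listed epithelial miRNAs were higher, with a median of 3.43 at the 99.9th percentile. miR-200b was 15.6-fold higher (15.1 to 16.2), miR-200a 15.1-fold (14.2 to 16.0) and miR-200c 12.6-fold (12.1 to 13.2); these are members of the miR-200 family, which maintains epithelial identity. These lists mark cell types other than NK cells that a uterine preparation could hold.

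All 56 listed miRNAs of the imprinted DLK1-DIO3 cluster were higher in uNK, with a median log2 value of 2.96 at the 100th percentile. miR-411a-5p was 15.4-fold higher (15.0 to 15.9), miR-379-5p 15.2-fold (14.7 to 15.7) and miR-127-3p 8.56-fold (8.23 to 8.90). The 6 listed arms of the X-linked miR-424 cluster were also higher, with a median of 2.59 at the 93.3rd percentile. Among them miR-424-5p was 13.7-fold higher (13.3 to 14.2), miR-542-5p 11.0-fold (10.2 to 11.8) and miR-450-5p 5.66-fold (5.07 to 6.34). Of the 6 listed miRNAs from Hox clusters, 5 were higher, with a median of 2.98 at the 96.3rd percentile; 4 of the 6 are also on the stromal list. miR-196b was 11.3-fold higher (11.2 to 11.5) and miR-10b-5p 14.5-fold (13.2 to 15.9).

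The 8 annotated miRNAs with the largest positive log2 values were miR-29c-3p, miR-199b-3p, miR-199c-5p, miR-199a-3p, miR-143-5p, miR-100-5p, miR-199a-5p and miR-200b. miR-29c-3p, of a family known to repress collagen genes, was 403-fold higher (300.0 to 555), at 590 against 1.46 RPM. Members of the miR-29 family are close in sequence and their reads could not be compared by sequence here, so this value is uncertain. miR-199c-5p was 36.0-fold higher (31.5 to 41.5), miR-143-5p 22.5-fold (18.7 to 27.3), miR-199a-3p 18.7-fold (18.2 to 19.2), miR-100-5p 16.8-fold (15.9 to 17.8) and miR-199a-5p 16.4-fold (15.1 to 17.8). The 3p arms named miR-199a, miR-199b and miR-199c are taken to be near-identical copies, which could not be checked by sequence here, so their single values are uncertain. Summed, these arms counted 31915 reads in pNK and 569871 in uNK.

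For the miRNAs higher in uNK, the pNK count was compared with the uNK count. Of 107 such miRNAs with at least 500 uNK reads, 46 had a pNK count of 5 to 8% of the uNK count, 57 lay above that range and 4 below it. Beside the muscle-enriched miRNAs, the median share was 6.78% over 19 stromal, 7.50% over 5 epithelial, 6.85% over 29 DLK1-DIO3 miRNAs and 12.7% over 4 miRNAs of the X-linked cluster. In the other direction, 37 of 123 miRNAs lower in uNK with at least 500 pNK reads had a uNK count under 5% of the pNK count, and 12 lay at 5 to 8%.

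**Figure D2:**
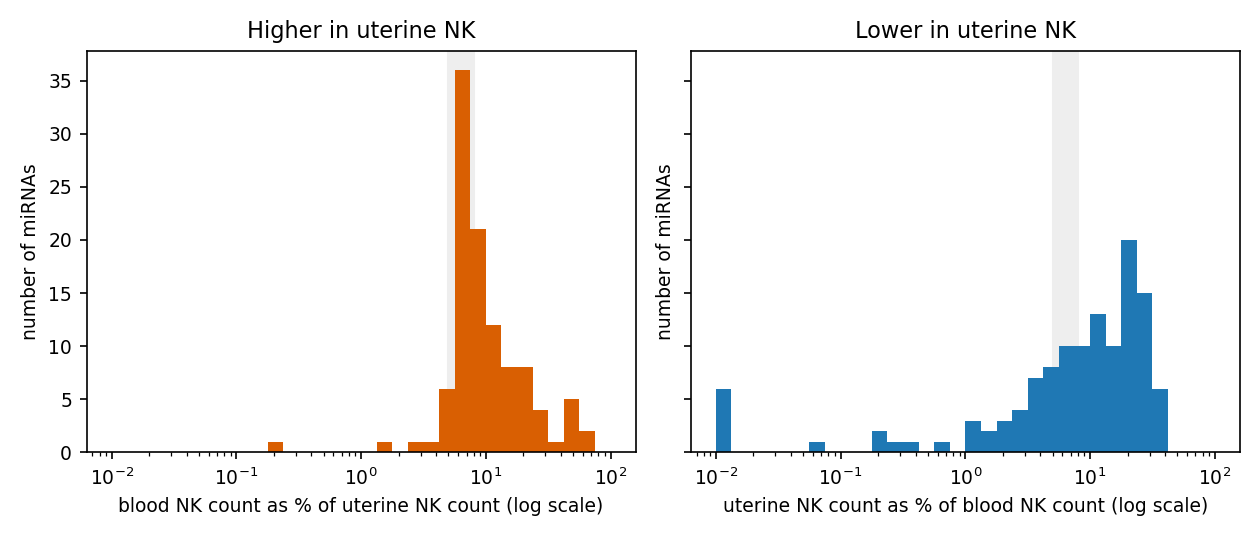
The left histogram shows the blood NK count as a percent of the uterine NK count for the 107 miRNAs higher in uterine NK with at least 500 reads there, and the right histogram shows the reverse for the 123 miRNAs lower in uterine NK with at least 500 blood NK reads; the horizontal axes are log scales, the vertical axis counts miRNAs, the grey band marks 5 to 8% and counts of 0 are drawn at the left edge. On the left 46 miRNAs lie in the band and 4 below it, whereas on the right 37 lie below 5%.

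Myeloid miRNAs were lower in uNK. Of the 14 listed members of the myeloid and platelet list, 12 were lower and 2 higher, with a median log2 value of -3.14 at the 0.43rd percentile. miR-223-3p, the main miRNA of granulocytes and monocytes, was 1508-fold lower (1390 to 1640), at 18.1 against 27243 RPM. miR-191-5p and miR-27a-3p, which many cell types express, were the other most abundant members. Of the lymphocyte list, 15 listed members were lower and 4 higher, with a median of -2.12 at the 5.76th percentile, inside the central 95% of matched random lists. Its 3 most abundant members were all lower. miR-150, which is high in mature lymphocytes, was 592-fold lower (557 to 630), at 32.2 against 19052 RPM. miR-155-5p, a regulator of lymphocyte activation, was 9.55-fold lower (9.27 to 9.84) and miR-26b-5p 3.75-fold lower (3.73 to 3.77).

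The miR-17-92 list holds that cluster and its paralogs, which promote proliferation, and also miR-92b. All 23 of its listed miRNAs were lower in uNK, with a median of -2.69 at the 0.13th percentile. miR-92a-3p was 8.33-fold lower (8.21 to 8.46), miR-93-5p 7.81-fold (7.71 to 7.92) and miR-25-3p 5.84-fold (5.73 to 5.94). All 10 listed miRNAs of the inflammation and activation list were lower as well, with a median of -2.85 at the 3.07th percentile, which is inside the central 95%; 5 of the 10 are on other lists too. Beside miR-21-5p and miR-155-5p, miR-146b-5p, a feedback inhibitor of inflammatory signalling, was 151-fold lower (135 to 169). The 8 annotated miRNAs with the largest negative log2 values were both arms of miR-223, miR-150, miR-146b-5p, miR-27a-5p, miR-211, miR-191-3p and miR-449a-5p. Of these miR-223-5p was 455-fold lower (373 to 561), miR-27a-5p 287-fold (191 to 453), miR-211 89.2-fold (78.8 to 101), miR-191-3p 54.2-fold (45.8 to 64.6) and miR-449a-5p 52.4-fold (42.9 to 64.8).

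The remaining lists were mixed, and their medians lay inside the central 95% of matched random lists. Of the 15 listed erythroid miRNAs, 5 were higher and 10 lower, with a median of -2.22 at the 11.3rd percentile. miR-451-5p, the most specific red cell miRNA of the list, was 3.01-fold higher in uNK (2.99 to 3.04), at 9800 against 3251 RPM, whereas miR-16a-5p and miR-16b-5p, which other blood cells also express, were 19.2-fold and 9.90-fold lower. Of the 5 endothelial members, both arms of miR-126 were higher. miR-222-3p was 11.0-fold lower (10.7 to 11.3) and miR-221-3p 5.71-fold lower (5.59 to 5.84), and the median of the list was -2.51 at the 23.5th percentile. Its summed level went the other way, at 5711 RPM in pNK and 11056 RPM in uNK. Of the 6 ciliated epithelium members, 1 was higher and 5 lower, with a median of -0.90 at the 71.9th percentile. Among these miR-34a was 4.86-fold lower (4.78 to 4.93) and miR-34c-3p, with 41 against 15 reads, 2.89-fold lower (1.57 to 5.62). The let-7 family divided into 5 higher and 6 lower, with a median of -1.48 at the 45.7th percentile. For let-7a, let-7f and let-7i only the 3p arm was listed. Summed over its listed members, the family stood at 17075 RPM in pNK and 40196 RPM in uNK, the other direction than its median. let-7c-5p was 13.4-fold higher (13.3 to 13.6) and let-7d-5p 3.76-fold lower (3.72 to 3.79). Of the 4 liver miRNAs, 2 were higher and 2 lower, and the sign of their median depended on the measure, at 0.07 with the pseudocount and -0.11 without it, with a mean of -0.59. The median with the pseudocount lay at the 64.3rd percentile. miR-192-5p was 12.7-fold lower (12.2 to 13.2), miR-194 2.23-fold higher (2.09 to 2.38) and miR-122 2.53-fold higher (1.77 to 3.68).

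**Figure D3:**
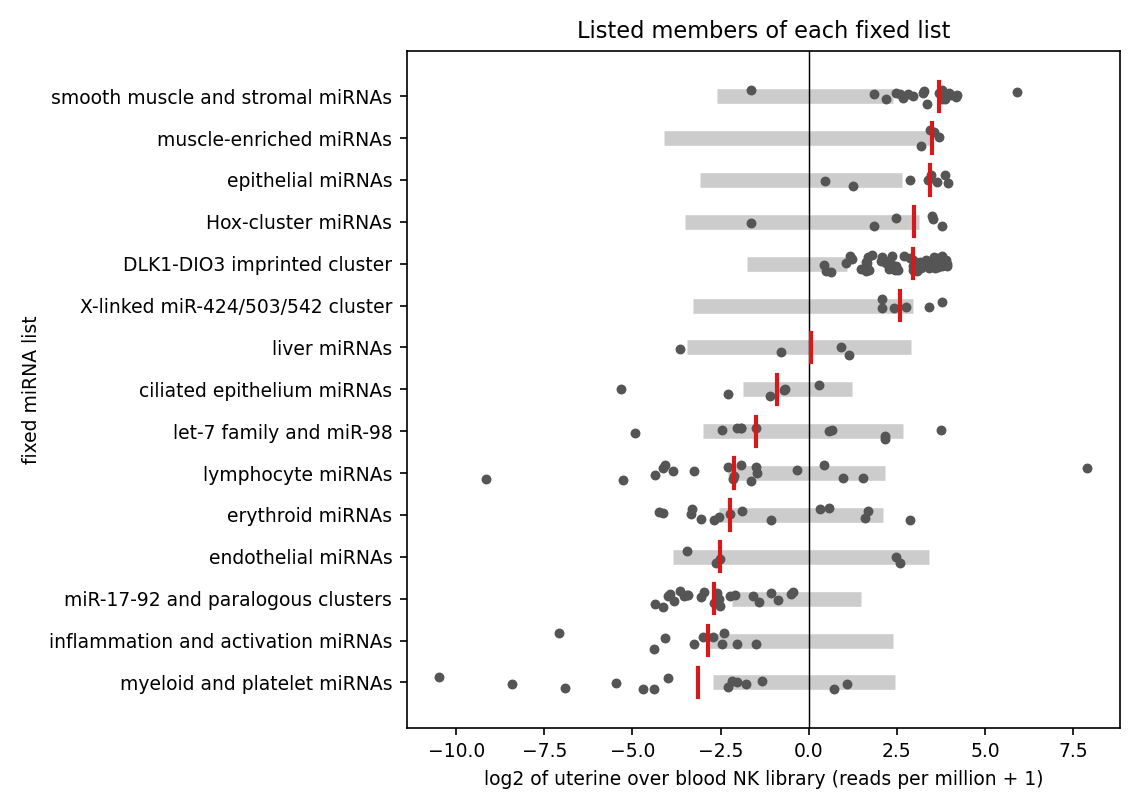
Each grey point is a listed miRNA of a fixed list, placed by its log2 ratio of uterine over blood NK libraries after adding 1 RPM; points are spread vertically for visibility. Red bars are list medians and grey bars the central 95% of medians of 10000 matched random lists; the stromal, muscle, epithelial and DLK1-DIO3 medians lie to the right of their grey bar and the miR-17-92 and myeloid medians to the left.

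The ratio of the arms of a precursor does not depend on the scaling between libraries. Both arms were listed for 94 precursors, and in 88 both arms had the same direction. The ratio of 5p over 3p differed by at least 1 log2 unit between the libraries in 54 of the 94, with a median difference of 0.01. Arms went in opposite directions for 6 precursors, which were named after their values were seen: miR-29c, miR-27b, miR-30a, miR-362, miR-10a and miR-34c. The largest difference was in miR-29c, where the 5p arm had 2387 reads in pNK and 92 in uNK and the 3p arm 44 and 18741 reads, with the same uncertainty in how reads of the miR-29 family were named.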

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

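No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Without a pseudocount no called direction turned under the scalings run, apart from 1 miRNA that lay exactly at the median ratio. The filter behind the table, which left no absolute log2 ratio under 1.01, largely fixes this beforehand. Relative to the RPM scale, the listed totals shifted every log2 value by 0.35, the median ratio by -0.67 and TMM by 0.74. Each was computed only on miRNAs called different, so none rests on unchanged miRNAs. The number of miRNAs higher in uNK ranged from 155 with a filter of 100 counts to 224, and stayed within 1.5 times the reported number under every alternative run. The number lower in uNK dropped from 366 to 182 with that filter and to 144 among annotated miRNAs. The drop to 144 leaves out the 222 predicted miRNAs that were lower, and the drop to 182 was not split by annotation. Under the other alternatives the number lower in uNK was 313 to 366. The log2 value of miR-1 was 3.50 with a pseudocount of 5 RPM, 3.91 with the listed totals, 2.90 with the median ratio and 4.31 with TMM, and 3.93 in the authors' deposited table, an alternative chosen after the data were seen. Between 6 and 7 of the 15 list medians were above 0 under each alternative, but their sizes moved. The ciliated epithelium median went from -0.90 to -3.80 with the filter of 100 counts and to -2.10 without a pseudocount. The DLK1-DIO3 median went from 2.96 to 1.76 with a pseudocount of 5 RPM. The erythroid median went from -2.22 to -1.06 without members on other lists, an alternative chosen after the data were seen. The liver median turned to -0.60 with the median ratio and to -0.11 without a pseudocount, the latter chosen after the data were seen, and the log2 value of miR-34c-3p, a miRNA with 41 and 15 reads, turned to 0.0587 with TMM and the pseudocount. Lists outside the central 95% of random lists numbered 6 with matching on abundance and 11 without it. The lists outside only without matching were the erythroid, lymphocyte, inflammation and activation, X-linked and Hox lists. The cause was not tested. Among annotated miRNAs only, the 10 most abundant took 80.1% of the listed annotated reads in pNK and 79.4% in uNK. Among all listed miRNAs, the 5 most abundant took 61.5% of the listed reads in pNK and 66.9% in uNK. With arms of at least 100 reads, 67 precursors were left, of which 5 had arms in opposite directions and 38 an arm ratio that differed by at least 1 log2 unit. Depth limits the miRNAs at 0 reads in a library (37 in pNK and 180 in uNK), for which only a bound of the fold can be given.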

Other observations

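The tests in this part were chosen after the values they bear on were seen, except the test of neighbouring miRNA genes. Its prediction was written before its result, but it is not independent of the list results above.

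Neighbouring miRNA genes moved together. In the goat assembly ARS1.2, 217 of the 220 annotated miRNA names of the table could be placed at 1 locus, giving 83 pairs of adjacent miRNA genes within 10 kb, of which 80 (96.4%) had the same direction against 50.1% after shuffling the directions (one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Without the DLK1-DIO3 cluster, 39 of 42 pairs (92.9%) shared their direction against 50.6% (one-sided permutation p = 1e-05). The other cluster lists were not left out. All 23 listed members of the miR-17-92 list were lower and all 6 of the X-linked list higher, so such a result could be foreseen in part. Each gene took the direction of its most abundant listed arm. The 3 pairs that parted were let-7a with let-7b, miR-23b with miR-27b, and miR-374b with miR-421. Such a split can depend on the arm listed. let-7a was listed only by its 3p arm (2644 reads in pNK and 979 in uNK), and the arms of miR-27b went in opposite directions. Where along miRNA production the differences arise was not tested. The arms of single precursors shared their direction in 88 of 94, although their ratio differed by at least 1 log2 unit in 54 of the 94. miRNA genes are not independent replicates, and the table holds only called miRNAs. let-7b-5p and let-7c-5p were higher in uNK, whereas miR-98-5p and let-7d-5p, of the same family, were lower.

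The median pNK counts of the muscle, stromal, epithelial and DLK1-DIO3 lists lay at 6.78 to 7.50% of the uNK counts, with upper quartiles up to 9.54%, and 4 of 107 miRNAs lay under 5%; a carry-over of uNK material into the pNK library at a few percent could set such a lower edge, and blood NK cells with a low level of these miRNAs of their own are an untested alternative. The test of that explanation stayed open: the highest list median of the pNK share was 1.87 times the lowest, between the limits of 1.5 and 2 set for it, because the median of the X-linked cluster was 12.7%, although its most abundant member, miR-424-5p, lay at 6.89%. miR-29c-3p, with 44 pNK reads or 0.235% of its uNK count, and miR-199c-5p, at 2.62%, go against a carry-over that is equal for all miRNAs, unless their reads were named differently in the 2 libraries, which could not be tested. The lower edge holds only for the 107 miRNAs with at least 500 uNK reads. Under that cut, where shares were not counted, miR-376e-5p of the DLK1-DIO3 list had 1 pNK read against 319 uNK reads. Of the miRNAs higher in uNK with at least 100 reads there, 1 had no pNK read. An equal exchange of reads in both directions is argued against by 6 miRNAs with at least 5000 pNK reads whose uNK count was under 1% of it, among them miR-223-3p at 0.0701%. For the miR-199 3p arms, taken to be near-identical, reads split differently between the 3 names may explain the outlying value of miR-199b-3p (1.56%). The 3 names together gave 5.60%. If carry-over is real, the fold of miR-1 would be a lower bound.

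Stromal, muscle and epithelial miRNAs were higher and myeloid miRNAs lower in the uNK library. A scaling constant between the libraries is argued against only as the cause of the gap between these lists. The stromal list median lay 6.83 log2 units above the myeloid one, and a constant moves both alike. These lists were compared after they were seen to lie apart. A constant as the cause of the sign of either median alone is not excluded, because no scaling here rests on unchanged miRNAs. Stromal, muscle and epithelial cells or their RNA in the uNK library stay open: 34 of 35 listed members (97.1%) of those 3 lists were higher there, but this restates the pattern and could only have excluded the explanation. The endothelial and ciliated lists, with 3 of 11 members (27.3%) higher, met the limit set for counting against the explanation. An exception, also written after the values were seen, left the test undecided. It applied because 6 of the 11 had over 1000 reads in pNK and a high level there hides a small contribution. Uterine NK cells that express these miRNAs themselves cannot be separated from other cells in bulk libraries and stay open, as do granulocytes or other leukocytes in the blood preparation as a source of miR-223-3p. Of the lymphocyte list, 15 listed members were lower in uNK and 4 higher, and miR-150 stood at 32.2 RPM in uNK against 19052 RPM in pNK. What this says of the cells in the uNK library was not tested.

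Predicted miRNAs were mostly lower in uNK, 222 of 276. Fewer reads in the whole uNK library are argued against, since its implied total was 1.06 times that of pNK. The listed miRNAs alone had fewer reads in uNK, 11884560 against 14291082 in pNK, but these totals include the called differences themselves. A loss of reads to miR-143-3p is argued against as the whole cause, since it lowers all other uNK miRNAs by 1 factor, of 0.25 log2 units, whereas annotated miRNAs were higher in uNK more often than predicted ones, by 34.6 percentage points. How the predictions were made is not given in the sources used here, and a prediction resting mainly on pNK reads stays open, as does a difference between the cells.

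In the authors' deposited table the q-value was below the p-value for all 427 miRNAs with a p-value above 0, by a factor of 0.051 to 0.192, and the largest listed p-value was 0.0159. Another 163 miRNAs are listed with a p-value of 0. The p-values compare 2 libraries and not 2 groups of animals.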
